A study of Mus musculus with 9 samples.

How the data were processed

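The 9 arrays hold total RNA of C2C12 mouse myoblasts treated with control, Cugbp1 or Mbnl1 siRNA and harvested at 0, 2.5 or 5 h after 5 ug/ml actinomycin D, with 1 array for each siRNA and time. Per the labels' protocols, RNA was extracted with an RNeasy kit and 100 ng of total RNA was labelled with biotin for Affymetrix whole-transcript sense arrays. Per the submitters' processing notes, values were made with RMA in Affymetrix Expression Console; the versions are not given in the sources used here. The deposited values are RMA intensity on the linear scale, which was read from the values themselves, and log2 was taken here. No value was missing or at or below 0. RMA brings arrays to a common distribution, so every change is relative to the other transcripts on the array and gives no absolute amount.

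The table has 35556 probe sets, of which 21789 have 1 gene symbol, 1621 several and 12146 none. Probe sets with 1 symbol represented 19938 genes. Those with a mean log2 of at least 7.385 (intensity 167.1, the 50th percentile of named probe sets) were kept, and for a gene with several probe sets the one with the highest mean was used. This left 9864 genes. The 3974 probe sets without a single symbol that passed the same filter were tested apart from them.

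Levels and changes over time were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on a model with siRNA and time as factors, which leaves 4 residual degrees of freedom. Decay was compared with a model that adds a straight line in hours per siRNA to the shared time course, with 2 residual degrees of freedom; the contrast is the difference in hourly slope. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Without replicate cultures the residual is the siRNA-by-time variation that a model leaves out. The fits were tested on simulated data with 200 changed genes, 100 per size. With changes of 0.25 the fit recovered 56 of 100 for the 5 h contrast and 49 for the level under Cugbp1 siRNA, with changes of 0.5 it recovered 95 for each, and 17 and 10 unchanged genes were called. For the decay under Cugbp1 siRNA it recovered 29 at 0.1 per h and 97 at 0.2 per h, with 12 unchanged genes called. No recovered gene had the wrong sign. Noise in these simulated data was drawn independently for each gene and array, with variances from the fitted prior. The counts therefore leave out differences between single cultures.

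There were 24 gene lists written as symbols: siRNA targets and their family, immediate early and other short-lived genes, cytosolic ribosomal proteins, glycolysis, oxidative phosphorylation, proteasome, myogenic regulators, muscle contraction, p53 targets, interferon response, replication, mitosis, extracellular matrix, cholesterol and fatty acid synthesis, unfolded protein response, heat shock, mRNA decay machinery, splicing factors, circadian clock, pathway regulators of Wnt, TGF-beta and Notch, and markers of adipocytes, osteoblasts and chondrocytes, fibroblasts, and macrophages and leukocytes. Others followed from symbols: Zfp genes, histones, small nucleolar RNAs and microRNA genes; mitochondrially encoded genes had 0 tested members. The lists, models, filter, thresholds, named genes rule and most alternatives were chosen before the data were examined. The rule for histones was written for older symbols and matched none of the current ones, so the older symbols of each gene were matched by gene ID; this was done after histones had been seen among the largest falls. Lists of at least 3 tested genes were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. No list call held with the estimated correlation. That setting also tests on the few residual degrees of freedom of the fit, so a lost call need not come from correlation between genes. For the regulators of Wnt, TGF-beta and Notch at 5 h the estimate was 0.00353, below the preset 0.01. Their unadjusted camera p still went from 3.08e-06 to 0.00761. This estimate was the lowest among the lists called at 5 h. The others had estimates above the preset, from 0.0244 for myogenic regulators to 0.385 for circadian clock genes. For them correlation between genes and the fewer degrees of freedom both raise p, and their shares were not separated. Fast-decaying mRNAs were the 10% of genes with the largest fall from 0 to 5 h in the arm outside the contrast. The knockdowns' effects were correlated across genes, and these correlations and the shared calls were set beside 100 simulations of unchanged arms against the same control arrays.

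Genes were named by rule: per comparison the 10 largest rises and 10 largest falls among called genes that went the same way in each array pair; where fewer than 5 passed, the 5 highest and 5 lowest moderated t; the 2 largest called changes of each list; and Celf1, Celf2, Mbnl1, Mbnl2, Mbnl3, Myod1, Myog, Myc, Fos, Jun, Cdkn1a, Gapdh and Actb. Myog, Fos, Cdkn1a and Gapdh had no probe set that passed. The level of Slbp under Mbnl1 siRNA is given outside this rule, after its values were seen.

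Alternatives were equal ribosomal protein medians on all arrays, no intensity filter, a filter at the 70th percentile, the mean of a gene's probe sets, a trended and robust moderation, each array left out in turn, only the arrays of the 2 siRNAs compared, other time terms, an estimated correlation for lists, and other sizes of the fast-decaying list. A fit without the Mbnl1 arrays, and the estimated correlation and equal ribosomal protein medians for fast-decaying mRNAs, were added after the data had been seen. A planned test of GU-rich and YGCY motifs was not run, because 3-prime untranslated region sequences are not among the sources used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.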

Results

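Total RNA of C2C12 cells, a mouse myoblast line, was hybridised to Affymetrix whole-transcript arrays after treatment with a control siRNA, an siRNA against Cugbp1 (current symbol Celf1) or an siRNA against Mbnl1. Both targets are RNA-binding proteins. RNA was collected at 0, 2.5 and 5 h after 5 ug/ml actinomycin D, which blocks transcription, so that the loss of an mRNA over time follows its decay. Each of the 9 combinations of siRNA and time had 1 array, which gives 3 arrays per siRNA and 3 per time. There are no replicates, and nothing in the labels says that the arrays came from separate cultures. All p-values therefore measure an effect against the siRNA-by-time variation that the model leaves out, and the number of arrays limits the precision. The median intensity of an array lay between 104.92 and 113.01, and the correlation of 2 arrays across probe sets between 0.980 and 0.998. The study asks whether the proteins affect mRNA decay. Of 19938 named genes, 9864 passed the intensity filter and were tested.

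Celf1 mRNA in the cells given Cugbp1 siRNA was at 30.9% of the control level at 0 h, 22.1% at 2.5 h and 21.6% at 5 h. Over the 3 times it was 4.08-fold lower, a log2 difference of −2.03 ± 0.09 (SE, n = 3 arrays per siRNA, limma adjusted p = 3.01e-05). Mbnl1 mRNA in the cells given Mbnl1 siRNA was at 22%, 18.3% and 15.9% of control at the same times, a log2 difference of −2.43 ± 0.09 (adjusted p = 1.63e-06). Mbnl1 siRNA also lowered Celf1, to 72.4%, 65.4% and 61.5% of control (log2 difference −0.59 ± 0.09, adjusted p = 0.000931). The converse was not seen: Mbnl1 differed from control by −0.07 ± 0.09 under Cugbp1 siRNA (adjusted p = 0.67). Among their relatives, Celf2 (−0.51 ± 0.04) and Mbnl3 (−0.37 ± 0.05) were lower and Mbnl2 (0.13 ± 0.04) was higher under Mbnl1 siRNA, and none of these 3 passed the test under Cugbp1 siRNA.

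**Figure D1:**
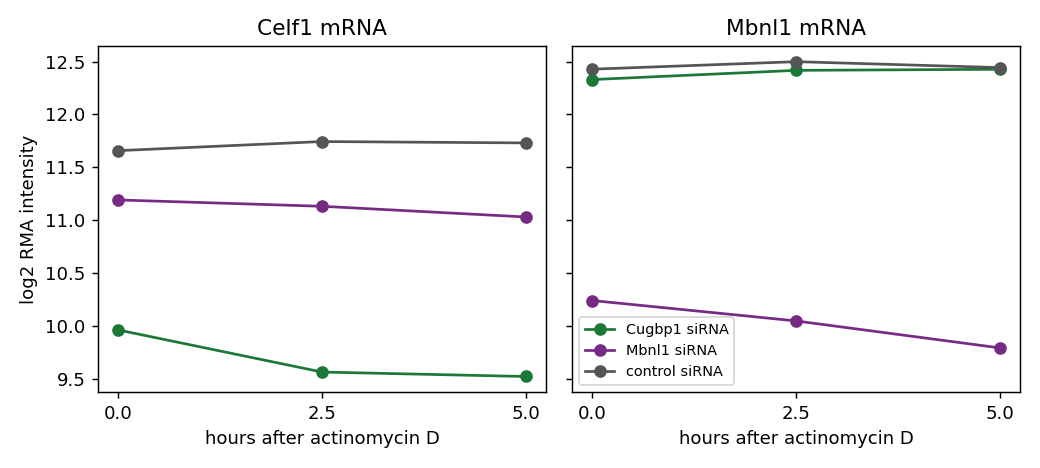
Celf1 and Mbnl1 mRNA on each of the 9 arrays, as log2 RMA intensity (vertical axis) against hours after actinomycin D, with 1 point per array and 1 line per siRNA. Each target was lowest with its own siRNA at all 3 times, and Celf1 also lay below control with Mbnl1 siRNA.

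The mRNAs of most histones and of immediate early and other short-lived genes fell within hours of transcription arrest. At 5 h the histone H2bc3 had fallen at least 18.5-fold (log2 change −4.21 ± 0.13, SE, n = 3 arrays per time). Here and below, a change is called a lower bound, or given as "at least", where the lower of the means compared lay under the filter value of 7.385. The mean log2 of H2bc3 at 5 h was 6.69. The filter value is the median of the named probe sets and not a measured background. That such sizes are too small is therefore an assumption about dim signal and was not tested. H1f5 fell 11.9-fold (−3.57 ± 0.12). Dusp1, a phosphatase of MAP kinases, fell 10.9-fold (−3.45 ± 0.08), and Id2, an inhibitor of basic helix-loop-helix factors, 8.56-fold (−3.10 ± 0.10). Ccn1 (−2.87 ± 0.13), Cited2 (−2.78 ± 0.11) and Myc (−2.37 ± 0.10) followed, and Jun fell by 1.57. Hes1 (−2.30 ± 0.08, a lower bound at a 5 h mean of 6.88) fell as well. Among the 10 largest rises against the rest were the small Cajal body RNA Scarna17 (1.44 ± 0.07), the nuclear long noncoding RNA Malat1 (1.21 ± 0.14), Mir505 (1.12 ± 0.09, a lower bound at a 0 h mean of 7.33) and Lncpint (0.94 ± 0.08), and the protein-coding genes Rsrp1 (0.84 ± 0.05), Slc9a5 (0.68 ± 0.08) and Atg9b (0.65 ± 0.06). All of these went the same way in each of the 3 siRNA arms, with adjusted p of 0.000146 or less. Actb, a cytoskeletal mRNA, differed by 0.02 ± 0.03 (adjusted p = 0.522) and, with every array shifted to the same ribosomal protein median, by −0.21 (adjusted p = 0.00338).

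Of the 17 histone genes measured, 16 fell at 5 h and 0 rose, with a median change of −2.21 (camera adjusted p = 1.88e-07, and 0.248 with an estimated correlation). Here and below, p-values with an estimated correlation also rest on the few residual degrees of freedom. Either these few degrees of freedom or correlation between genes can undo a call, and the p-values do not tell the 2 apart. The estimated correlation was 0.282 for histones, against the preset 0.01. Near-identical histone genes can share probe signal, so the value of a single histone is uncertain. Of 48 immediate early and other short-lived genes, 46 fell (median −1.23, adjusted p = 6.66e-16, and 0.203 with an estimated correlation). Zinc finger genes named Zfp fell in 123 of 154 cases (median −0.50, adjusted p = 1.88e-15, and 0.203 with an estimated correlation), with Zfp51 at −2.11 (a lower bound at a 5 h mean of 7.09) and Zfp213 at −1.88, while 6 rose. Regulators of Wnt, TGF-beta and Notch signalling fell in 20 of 24 cases (median −0.68, adjusted p = 1.38e-05, 0.144 with an estimated correlation), among them the receptor Fzd7 (−1.68 ± 0.06). Circadian clock genes fell in 8 of 11 cases (median −0.42, adjusted p = 0.00498, 0.502 with an estimated correlation), with Bhlhe40 at −2.20 and Bhlhe41 at −1.71. Among 18 myogenic regulators 9 fell and 0 rose (median −0.12, adjusted p = 0.00964, 0.248 with an estimated correlation), including Myf5 (−1.29 ± 0.04) and Myod1 (−0.85 ± 0.05). With equal ribosomal protein medians all 18 fell, at a median of −0.35 (adjusted p = 0.0074). Of 19 p53 targets 10 fell and 3 rose (median −0.36, adjusted p = 0.0418, 0.622 with an estimated correlation); with equal ribosomal protein medians 14 fell and 0 rose, at a median of −0.60, and the list was no longer called (0.0668). Among them Plk2 stood at −2.20. Genes of G2/M and mitosis fell in 24 of 44 cases and rose in 4 (median −0.14, adjusted p = 0.0141, 0.569 with an estimated correlation), led by the cyclin Ccnf (−2.14 ± 0.15). Equal ribosomal protein medians turned these counts to 37 lower and 0 higher, at a median of −0.38 (adjusted p = 0.00606). Adjusted over the list alone, the falling members numbered 16 histones, 46 immediate early genes, 124 Zfp genes, 20 pathway regulators, 8 clock genes, 9 myogenic regulators, 10 p53 targets and 24 mitotic genes.

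Nuclear-encoded subunits of oxidative phosphorylation rose relative to the other transcripts in 47 of 55 cases (48 adjusted over the list alone), with a median of 0.25. As deposited the camera adjusted p was 1.74e-09, and 0.144 with an estimated correlation. When every array was shifted to the same ribosomal protein median 11 rose and 7 fell, with a median of 0.01. The median of all genes was then −0.199, and the list was still called against the other genes (camera adjusted p = 1.23e-11). Cytosolic ribosomal protein genes rose in 44 of 54 cases (45 adjusted over the list alone; median 0.18, adjusted p = 1.88e-07, 0.203 with an estimated correlation), a direction that this shift turns to −0.05, as its construction requires. This list too was still called against the other genes after the shift (camera adjusted p = 8.19e-07). Rpl12 was the only ribosomal protein gene that fell as deposited (−1.74 ± 0.13, a lower bound at a 5 h mean of 6.86). Its probe set was far dimmer than the ribosomal protein median of the 5 h arrays (12.63 to 12.71), so its value is uncertain. After the shift 7 ribosomal protein genes fell and 6 rose. Proteasome subunits rose in 12 of 31 cases and fell in 1 (11 and 1 adjusted over the list alone; median 0.09, adjusted p = 0.0198, 0.421 with an estimated correlation), which the shift turns to 0 higher and 18 lower, with a median of −0.14 and an adjusted p of 0.413. MicroRNA genes rose in 24 of 34 cases (also 24 adjusted over the list alone; median 0.21, adjusted p = 0.000397, 0.502 with an estimated correlation), which the shift turns to 3 higher and 5 lower, with a median of −0.02. Against the other genes they were still called (camera adjusted p = 8.29e-06).

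In all, 3514 genes rose and 3232 fell at 5 h (limma, adjusted p under 0.05), of which 6669 went the same way in all 3 arms. The falls were larger: 542 genes fell and 3 rose by more than 1 on the log2 scale. In single arms, 608 genes fell at least 2-fold with control siRNA, 451 with Cugbp1 siRNA and 622 with Mbnl1 siRNA, and 389 did so in all 3. These values are relative, since RMA sets arrays to a common distribution. Equal ribosomal protein medians moved the median of all genes by −0.23 and the split from 52.1% higher to 4.6% higher (281 higher, 5855 lower).

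**Figure D2:**
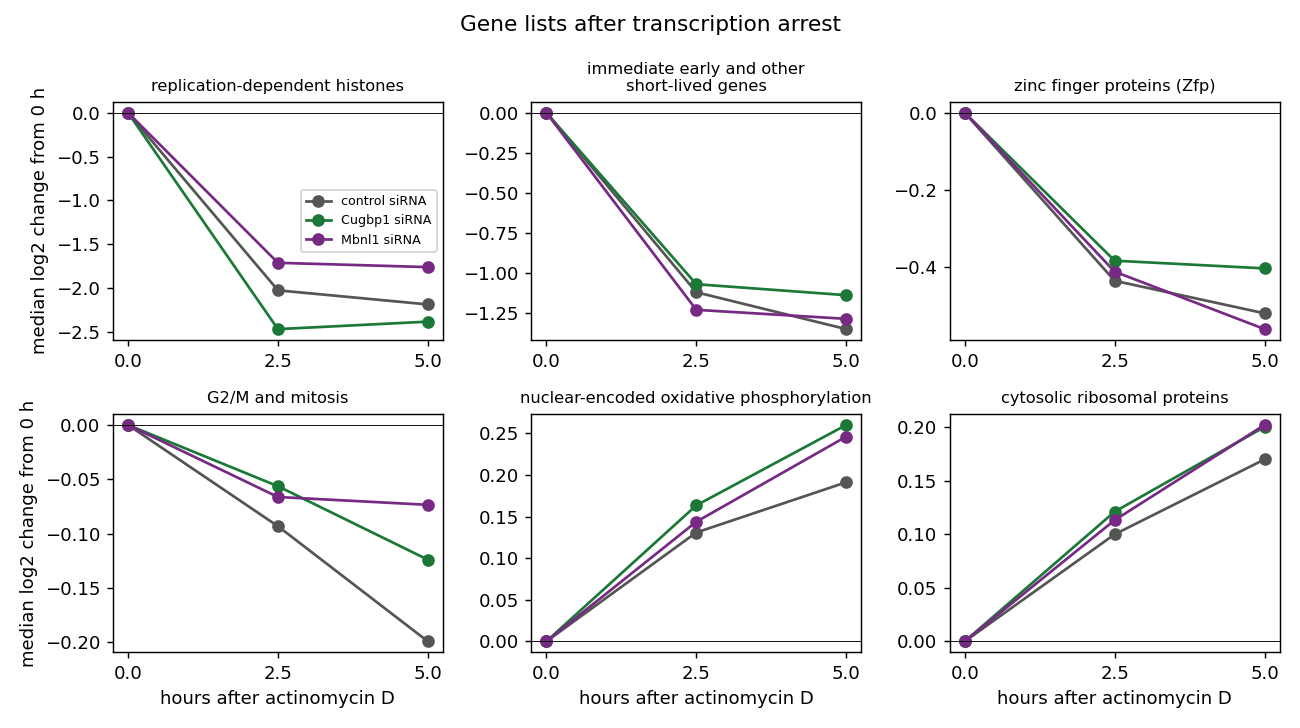
Median log2 change from 0 h (vertical axis, with a scale of its own in each panel) against hours after actinomycin D for 6 gene lists, with 1 line per siRNA and each point the median over the list's genes on 1 array. Histones, short-lived genes, Zfp genes and mitotic genes declined in all 3 arms. Oxidative phosphorylation and ribosomal protein genes rose relative to the rest. With equal ribosomal protein medians their 5 h medians over the arms were 0.01 and −0.05, against −0.199 for all genes.

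At 2.5 h the fastest of these losses had already taken place. H2bc3 had fallen at least 16.4-fold (−4.04 ± 0.13, n = 3 arrays per time; mean log2 6.86, also under the filter value), H1f5 11.9-fold (−3.57 ± 0.12) and Dusp1 11.2-fold (−3.48 ± 0.08). Myc (−2.44 ± 0.10), Hes1 (−2.45 ± 0.08, a lower bound at a mean of 6.73) and Jun (−1.86 ± 0.07) fell as well, while Cited2 stood at −1.62 ± 0.11 and Myod1 at −0.42 ± 0.05, with adjusted p of 0.000447 or less in each case. Malat1 had risen by 1.17 ± 0.14. Of the short-lived genes 46 of 48 fell (46 adjusted over the list alone; median −1.12, camera adjusted p = 9.68e-24, 0.134 with an estimated correlation). Of the histones 16 of 17 fell (also 16 over the list alone; median −1.98, adjusted p = 1.03e-10, 0.192 with an estimated correlation). Of the oxidative phosphorylation genes 33 of 55 rose (36 over the list alone; median 0.15, adjusted p = 5.15e-08, 0.134 with an estimated correlation). With equal ribosomal protein medians 6 rose and 0 fell, with a median of 0.04 against −0.0742 for all genes. The list was then still called (camera adjusted p = 5.33e-08). In total 2283 genes were higher and 2391 lower. The higher count became 1228 without the Cugbp1 array at 2.5 h, 1290 without the control array and 1498 without the Mbnl1 array at that time. Equal ribosomal protein medians moved the median of all genes by −0.11 and gave 238 higher and 3240 lower.

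Cugbp1 siRNA changed the level of a few genes by 2-fold or more over the 3 times, besides Celf1 itself. The histone H2bc4 was 3.14-fold higher than with control siRNA (log2 difference 1.65 ± 0.05, SE, n = 3 arrays per siRNA). Prr9 (1.496 ± 0.048), Ly6g (1.40 ± 0.12), Hmox1, which encodes the haem-degrading heme oxygenase (1.27 ± 0.09), Gpnmb (1.21 ± 0.08), Lbp, the lipopolysaccharide binding protein (1.20 ± 0.05), and Ppargc1a, a coactivator of mitochondrial gene expression (1.10 ± 0.16), were higher too. Ccdc73 (−1.27 ± 0.07), Sgms2, a sphingomyelin synthase (−1.22 ± 0.07), Tor1aip2 (−1.10 ± 0.08), Erlin2 (−1.09 ± 0.04) and Tmem123 (−1.05 ± 0.04) were lower. Each went the same way at all 3 times, with adjusted p of 0.00382 or less. The values of Prr9, Ly6g and Ppargc1a are lower bounds, since their control means were 7.20, 7.25 and 6.85. Slbp, which binds the stem-loop of histone mRNAs, was 1.88-fold lower (−0.91 ± 0.05, adjusted p = 4.24e-05). In the mRNA decay machinery the exonuclease Xrn1 was higher (0.68 ± 0.05) and the decapping enzyme Dcp2 lower (−0.45 ± 0.09); the receptor Notch1 was higher (0.77 ± 0.05). Myod1 differed by 0.11 ± 0.05 and Myc by 0.10 ± 0.10, neither of which passed.

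By list, oxidative phosphorylation genes stood slightly higher under Cugbp1 siRNA (median 0.06; 5 of 55 rose, 0 adjusted over the list alone; camera adjusted p = 0.00738, 0.955 with an estimated correlation). Extracellular matrix and adhesion genes stood slightly lower (median −0.06; 11 of 39 fell and 7 rose, 13 and 7 adjusted over the list alone; adjusted p = 0.0268, also 0.955 with an estimated correlation), with the protease Adamts1 at −0.47 and its inhibitor relative Timp3 at −0.46. With equal ribosomal protein medians neither list was called, at medians of 0.04 (adjusted p = 0.0588) and −0.09 (0.0862). No other list was called. The mRNA decay machinery had 5 of 42 genes higher and 3 lower, the same counts adjusted over the list alone (median 0.0155, −0.0067 with equal ribosomal protein medians). Of cholesterol and fatty acid synthesis genes 3 of 24 were higher and 2 lower, also the same over the list alone (median 0.0177, −0.0045 with equal ribosomal protein medians). Heat shock genes were higher in 1 of 15 cases and lower in 2, small nucleolar RNAs higher in 2 of 20 and lower in 0, and interferon response genes higher in 1 of 12 and lower in 0, each with the same counts over the list alone. Of glycolysis genes 3 of 14 were lower and 0 higher (3 and 1 over the list alone). Of the 17 histones 4 were higher and 2 lower (also 4 and 2 over the list alone; median 0.0199, −0.0023 with equal ribosomal protein medians). In all, 1039 genes were higher and 855 lower, and the median absolute difference over all genes was 0.07. With equal ribosomal protein medians the split was 522 higher and 712 lower (42.3% higher against 54.9%), and the total of 1894 became 1234. Without 1 array it was 742 (control, 2.5 h), 759 (Cugbp1, 2.5 h), 995 (control, 5 h), 1060 (Cugbp1, 5 h) or 1199 (control, 0 h).

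**Figure D3:**
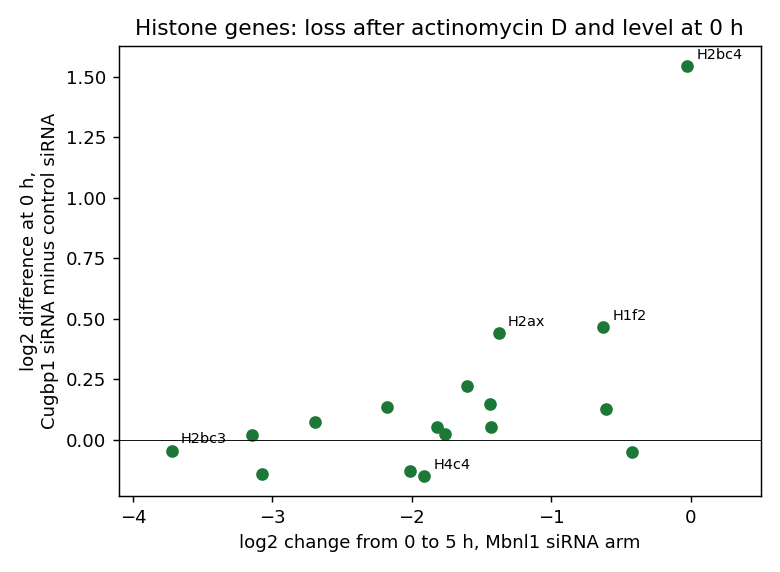
Log2 difference in level at 0 h between Cugbp1 and control siRNA (vertical axis) against the log2 change from 0 to 5 h in the Mbnl1 siRNA arm (horizontal axis), with 1 point per histone gene, 17 in all, each from single arrays. H2bc4, which barely declined in that arm (−0.025), stood 1.54 above control at 0 h.

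Under Mbnl1 siRNA 69 genes were higher and 78 lower by more than 1 on the log2 scale, against 9 and 7 under Cugbp1 siRNA. The kallikrein protease Klk6 was at least 12.1-fold higher than with control siRNA (log2 difference 3.59 ± 0.06, SE, n = 3 arrays per siRNA). Ly6g (2.86 ± 0.12), Il1rn, the interleukin receptor antagonist (2.75 ± 0.05), the keratin Krt8 (2.69 ± 0.05), Prr9 (2.66 ± 0.05), the metalloproteinases Mmp12 (2.57 ± 0.17) and Mmp10 (2.54 ± 0.08) and Penk, the enkephalin precursor (2.42 ± 0.07), were higher as well. After Mbnl1 itself, the largest falls were those of the syndecan Sdc3 (−1.87 ± 0.15), Depdc1a (−1.79 ± 0.14), Minpp1 (−1.79 ± 0.21), Pafah1b1 (−1.72 ± 0.17), the dynein subunit Dync1li1 (−1.71 ± 0.25), Mrpl36 (−1.61 ± 0.13) and Pimreg (−1.60 ± 0.09). Each went the same way at all 3 times, with adjusted p of 0.00073 or less. The values of Klk6, Ly6g, Prr9 and Mmp12 are lower bounds, since their control means were 6.44, 7.25, 7.20 and 7.01.

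Every gene of the S phase and DNA replication list fell under Mbnl1 siRNA, 36 of 36 (36 adjusted over the list alone), with a median of −0.41 as deposited and with equal ribosomal protein medians. Pola1, the catalytic subunit of DNA polymerase alpha, stood at −0.84 ± 0.05. Genes of G2/M and mitosis fell in 43 of 44 cases (43 over the list alone; median −0.59, −0.58 with equal ribosomal protein medians), with the kinetochore gene Nuf2 at −1.01 ± 0.04. Camera gave adjusted p = 1.01e-11 for the first list and 7.32e-16 for the second, and 0.62 and 0.587 with an estimated correlation. Genes of muscle contraction and differentiation rose in 17 of 24 cases and fell in 1 (18 and 2 over the list alone; median 0.26 in both scalings, adjusted p = 8.14e-05, 0.62 with an estimated correlation), among them the troponins Tnni1 (1.14 ± 0.05, a lower bound at a control mean of 7.30) and Tnnt3 (1.05 ± 0.06). The myogenic regulators Myod1 (−0.58 ± 0.05) and Cdh15 (−0.58 ± 0.04) were lower; of that list 5 of 18 fell and 3 rose. Splicing factors fell in 17 of 36 cases and rose in 1 (17 and 1 over the list alone; median −0.10), and the mRNA decay machinery fell in 21 of 42 and rose in 4 (22 and 4 over the list alone; median −0.14), with the Argonaute gene Ago2 at −0.67 and Tob1 at 0.74. Both lists had adjusted p = 0.0416, and 0.779 with an estimated correlation. Oxidative phosphorylation genes rose in 14 of 55 and fell in 1 (8 and 0 over the list alone; median 0.05, adjusted p = 0.0416, 0.767 with an estimated correlation). With equal ribosomal protein medians the replication, mitosis and muscle lists were still called under Mbnl1 siRNA, while oxidative phosphorylation and the mRNA decay machinery (both adjusted p = 0.0641) and splicing factors (0.0671) were not, at medians that barely moved (0.05, −0.14 and −0.10). Of the short-lived genes 22 of 48 rose and 10 fell (median 0.19, adjusted p = 0.0769), with the polo-like kinase Plk3 at 1.62 ± 0.15 and the prostaglandin synthase Ptgs2 at 1.42 ± 0.05. Clock genes went both ways, Nr1d2 at −1.41 and Clock at −1.16 among the 5 of 11 that fell, with 4 that rose. Unfolded protein and integrated stress response genes rose in 12 of 28 cases and fell in 6 (median 0.07, adjusted p = 0.113).

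Markers of other cell types were few on the array at this level. Of 3 fibroblast and fibro-adipogenic markers 2 rose and 1 fell under Mbnl1 siRNA, with decorin (Dcn) at 1.14 ± 0.05 and Cd34 at 0.50 ± 0.05; of 4 adipocyte markers 0 changed, and of 3 osteoblast and chondrocyte markers 1 rose, Col2a1 (0.11 ± 0.04). None of these lists was called (adjusted p from 0.21 to 0.656). Only 2 macrophage and leukocyte markers passed the intensity filter, too few to test. In all, 2372 genes were higher and 3054 lower under Mbnl1 siRNA.

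**Figure D4:**
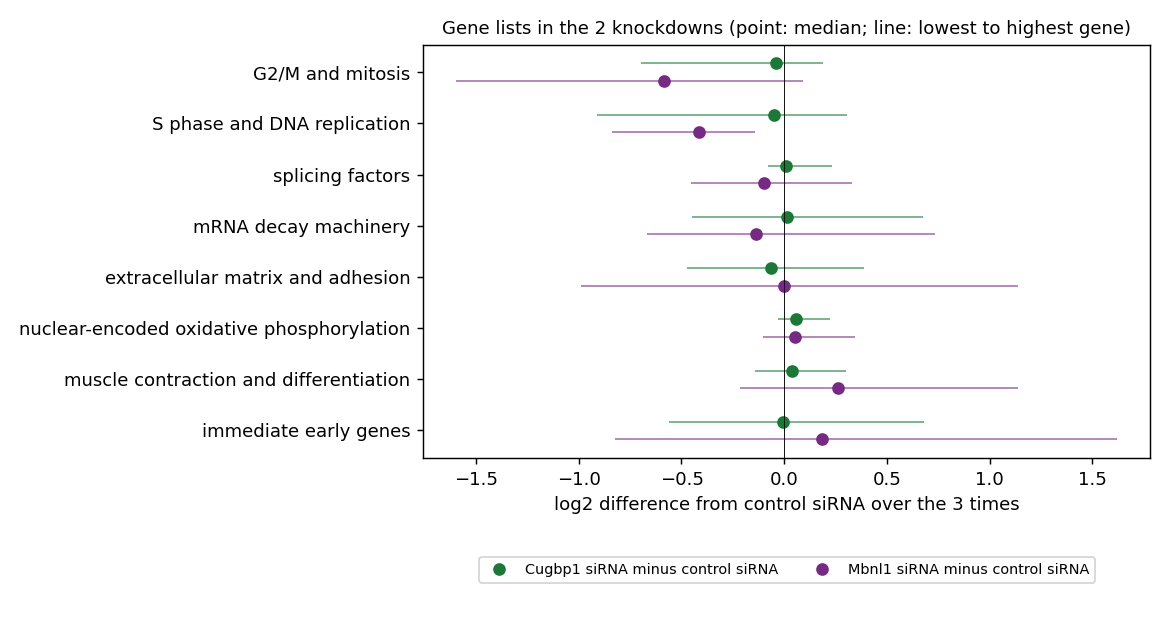
Log2 difference in level between each knockdown and control siRNA over the 3 times (horizontal axis) for 8 gene lists, with a point at the list's median and a line from its lowest to its highest gene. Replication and mitosis genes lay lower with Mbnl1 siRNA, at medians of −0.41 and −0.59, and close to 0 with Cugbp1 siRNA, at −0.05 and −0.04.

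Compared directly, the knockdowns differed most in Klk6, which was at least 13.5-fold higher under Mbnl1 siRNA than under Cugbp1 siRNA (3.75 ± 0.06, SE, n = 3 arrays per siRNA). Il1rn was 8.61-fold higher (3.11 ± 0.05) and Mmp12 at least 8.32-fold higher (3.06 ± 0.17). Lower under Mbnl1 siRNA were the histone variant gene H2ax (−1.91 ± 0.11), Lbp (−1.90 ± 0.05) and Ctns, the lysosomal cystine transporter (−1.68 ± 0.25). All had adjusted p of 0.000822 or less and the same direction at all 3 times. The values of Klk6 and Mmp12 (means of 6.29 and 6.52 under Cugbp1 siRNA) and of Lbp (7.07 under Mbnl1 siRNA) are lower bounds. Mitotic genes were lower in 42 of 44 cases (42 adjusted over the list alone; median −0.58, adjusted p = 8.73e-14, 0.735 with an estimated correlation) and replication genes in 34 of 36, with 1 higher (35 and 1 over the list alone; median −0.35, adjusted p = 9.67e-09, 0.735 with an estimated correlation). Muscle genes were higher in 17 of 24 and lower in 2 (18 and 2 over the list alone; median 0.25, adjusted p = 0.00011, 0.735 with an estimated correlation). Counts were 2268 higher and 3295 lower.

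In level 525 genes were called higher in both knockdowns, 394 lower in both and 367 in opposite directions. Independent lists of these sizes, which leave out that the control arrays are shared, would give 249.8, 264.7 and 527.3. Unchanged arms simulated against the same control arrays, which leave out any effect, gave at most 1, 0 and 0, and part of the excess in calls may come from the shared controls. Gpnmb, Prr9, Ly6g, Hmox1 and H2bc4 rose in both. Across genes, which are not independent replicates, the level effects had Pearson r = 0.224 and Spearman rho = 0.240. Both effects share the control arrays, and unchanged arms simulated against those arrays gave r = 0.498. Unchanged arms with equal noise give about this r whatever the data. A lower observed r therefore does not mean that the knockdowns were less alike than unchanged arms. The covariance was 0.0115 against 0.00151 in the simulation, and effects taken from different control arrays had a mean covariance of 0.0102 and r of 0.151 to 0.197. Those control arrays are other times of the single control siRNA series. A deviation of that whole series would enter both effects, so this covariance does not show a shared effect of the knockdowns. For the differences in decay the covariance exceeded the simulated value by 8.26e-06, at r = 0.350 against 0.499 simulated. The simulated noise was taken from the siRNA-by-time residual, which holds any difference in decay. This comparison therefore cannot tell whether the knockdowns share an effect on decay.

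The decay of single mRNAs was compared as the difference in hourly log2 slope, positive where an mRNA declined less. Under Cugbp1 siRNA no gene passed (0 higher and 0 lower in limma, 1129 at an unadjusted p under 0.05, smallest adjusted p = 0.32). The highest ratios of effect to error belonged to the linker histone H1f2 (0.120 ± 0.016 per h, SE), Zfp869 (0.137 ± 0.019), Zfp318, Tfam and Zbtb1, and the lowest to the histone H4c4 (−0.279 ± 0.034 per h), the mitotic kinase Plk1 (−0.130 ± 0.016), Tesc, Ehd4 and Iars. The remaining Celf1 mRNA had a slope difference of −0.103 ± 0.028 per h, Myc of 0.053 ± 0.029 and Tnfaip3, an inhibitor of NF-kappaB signalling, of 0.174 ± 0.026, all with adjusted p of 0.32 or more.

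As a group, mRNAs that decay fast declined less under Cugbp1 siRNA. The 10% of genes with the largest fall in the Mbnl1 arm, which this contrast does not use, were 986 genes. Their median change at 5 h was −0.95 with Cugbp1 siRNA and −1.08 with control siRNA, and 78.2% of them had a positive slope difference against 63.8% of the other genes (medians of 0.0252 and 0.0082 per h; camera adjusted p = 1.06e-05 over the 3 decay contrasts, and unadjusted p = 0.228 with an estimated correlation). With equal ribosomal protein medians 62.5% against 40.7% were positive, with medians of 0.0114 and −0.0056 per h. The histone list was not called (median slope difference 0.0063 per h, −0.0075 with equal ribosomal protein medians; camera adjusted p = 0.293): its median change at 5 h was −2.38 with Cugbp1 siRNA and −2.18 with control siRNA. Adjusted over the list alone 5 of 17 histones declined faster and 3 slower, and 0 were called over all genes. Immediate early and other short-lived genes had a median slope difference of 0.033 per h (adjusted p = 0.042, 0.981 with an estimated correlation; 1 of 48 called adjusted over the list alone). Muscle contraction genes lay the other way (median −0.0265 per h, adjusted p = 3.17e-07, 0.65 with an estimated correlation, 1 of 24 called over the list alone), with the myosin light chain Myl1 at −0.125 ± 0.023, and so did microRNA genes (median −0.0235 per h, adjusted p = 1.56e-06, 0.736 with an estimated correlation, 0 called over the list alone). Equal ribosomal protein medians moved these medians to 0.0192 per h for short-lived, −0.0403 for muscle and −0.0373 for microRNA genes. Each list was still called.

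Under Mbnl1 siRNA 2 genes declined faster than in the control arm and 0 slower. Ctns had a slope difference of −0.300 ± 0.021 per h and Dync1li1 of −0.304 ± 0.022 per h (both adjusted p = 0.0279, in the same direction at 2.5 h and 5 h; Ctns ended at 7.21, under the filter value). Dync1li1 stood at −0.89 against control at 0 h, −1.82 at 2.5 h and −2.41 at 5 h. Minpp1 (−0.238 ± 0.023 per h), R3hcc1 (−0.197 ± 0.019) and Ppfibp1 (−0.173 ± 0.016) came next and did not pass (adjusted p = 0.0514). The remaining Mbnl1 mRNA had a slope difference of −0.092 ± 0.016 per h (adjusted p = 0.098). Histones declined less as a group (median 0.0791 per h, 0.0508 with equal ribosomal protein medians, camera adjusted p = 3.12e-07, 0.579 with an estimated correlation). Of the 17, 8 were called adjusted over the list alone and 0 over all genes, with H2bc14 at 0.168 ± 0.019. All but H1f2, H2ac1 and H2bc4 already stood below control on the single Mbnl1 array at 0 h, H1f5 by −0.794 and H2bc18 by −1.129. The median histone change in this arm was −1.71 at 2.5 h and −1.76 at 5 h. A lower start at 0 h and slower decay are therefore not told apart. Replication genes (median 0.0234 per h, adjusted p = 6.04e-05) and mitotic genes (median 0.0191 per h, adjusted p = 0.00125) also lay above the other genes, both at 0.579 with an estimated correlation. With equal ribosomal protein medians both lay below 0, at −0.005 and −0.0093. The median of all genes was then −0.0272, and both lists were still called (camera adjusted p = 0.000198 and 0.000827). The 4 mitotic genes and 0 replication genes called over the list alone were higher. The siRNA target family lay lower (median −0.0304 per h, adjusted p = 0.025, 0.579 with an estimated correlation, 0.0525 with equal ribosomal protein medians at a median of −0.0588, 1 of 7 called over the list alone). The 986 genes with the largest fall in the Cugbp1 arm had a median slope difference of 0.0102 per h under Mbnl1 siRNA, with 58.2% positive against 50.8% of the others, a direction that equal ribosomal protein medians turn to −0.0182 per h, against −0.0278 for the others (camera adjusted p = 0.0127 over the 3 contrasts, and unadjusted p = 0.472 with an estimated correlation). The count of 2 became 203 without the Mbnl1 array at 2.5 h, 7 without that at 5 h, and 0 without the control array at 0 h or 5 h, the Mbnl1 array at 0 h or any 1 of the Cugbp1 arrays. Equal ribosomal protein medians gave 295.

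Between the knockdowns 84 mRNAs declined faster and 9 slower under Mbnl1 siRNA than under Cugbp1 siRNA. Faster were Ctns (−0.296 ± 0.021 per h, SE), Dync1li1 (−0.284 ± 0.022), Minpp1 (−0.258 ± 0.023), the Myc antagonist Mxd1 (−0.229 ± 0.023), Btg2 (−0.213 ± 0.032) and Ppargc1a (−0.205 ± 0.019). Slower were the histones H4c4 (0.284 ± 0.034), H4c6 (0.227 ± 0.029), H2bc14 (0.188 ± 0.019) and H1f1 (0.157 ± 0.022) and the cell cycle genes Plk3 (0.183 ± 0.022), Ccnf (0.164 ± 0.023) and Plk1 (0.145 ± 0.016). All had adjusted p of 0.0477 or less and the same direction at 2.5 h and 5 h. Among the lists, histones had the largest difference (median 0.1125 per h, adjusted p = 1.9e-10, 0.37 with an estimated correlation). Of the 17, 4 were slower and 0 faster, and 12 and 2 adjusted over the list alone. The low start of most histones on the Mbnl1 array at 0 h enters this contrast too. The p53 targets lay the other way (median −0.0287 per h, 2 of 19 faster and 0 slower, 6 and 0 over the list alone; adjusted p = 0.00466, 0.37 with an estimated correlation). For the 986 genes with the largest fall in the control arm the median was −0.0167 per h, which did not pass (camera adjusted p = 0.216). The count of 93 became 474 without the Mbnl1 array at 2.5 h, 43 without that at 5 h, 33 without any 1 of the control arrays, and 0 without the Mbnl1 array at 0 h or any 1 of the Cugbp1 arrays. It was 0 with no intensity filter and 355 with equal ribosomal protein medians.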

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

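The tests on histones, on slopes from 2.5 to 5 h and the 5 h test of compressed changes were chosen after the result was seen. The other tests in this part were written down before their results, the 2.5 h test of compressed changes after the 5 h result was known.

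Ctns and Dync1li1 declined faster with Mbnl1 siRNA than with control siRNA, by −0.3001 and −0.3037 per h on the log2 scale, a difference between siRNAs that passed its own test. Both were called between the knockdowns too, at −0.2959 and −0.2838. Faster with Mbnl1 than with Cugbp1 siRNA were also Minpp1 (−0.2581), Mxd1 (−0.2292), Btg2 (−0.2131), Ppargc1a (−0.2045), Prune1 (−0.2036), Pafah1b1 (−0.2022), Zfp617 (−0.1942), Mir100hg (−0.194), Trp53inp1 (−0.1557), Zfp386 (−0.1414) and the remaining Mbnl1 mRNA (−0.109). Slower were H4c4 (0.2836), H4c6 (0.2267), H2bc14 (0.1881), Plk3 (0.1828), Ccnf (0.1643), H1f1 (0.1572), Plk1 (0.1446), Zfp524 (0.1185) and Vax1 (0.1089). Among probe sets without a single gene symbol, which the comparisons do not use, 77 differed in level with Cugbp1 siRNA and 850 with Mbnl1 siRNA.

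In the Mbnl1 arm, mRNAs already low at 0 h fell faster afterwards. The 50 genes lowest against control at 0 h, Mbnl1 left out, had a median slope difference of −0.0396 per h, below the range of random lists matched on expression (−0.0084 to 0.0114), where noise in the 0 h array would give a value at or above 0. They were not short-lived in general, since their median 5 h change in the control arm was 0.0505. Transcripts destabilised by the siRNA itself or by loss of Mbnl1 and differences between single cultures may contribute. The 50 highest genes also declined faster (−0.0214 per h), a value that 0 h noise alone would push below 0. From 2.5 to 5 h, without the 0 h arrays, highest (−0.0318) and lowest (−0.0268) both lay below their random ranges (from −0.0199 and −0.0177 up). Members went both ways there: 31 of the highest lay below 0 and 19 above, and 28 of the lowest below and 22 above. In the Cugbp1 arm the 50 lowest (0.0088 per h) and highest (−0.0034) decide neither noise nor destabilised transcripts, since the choice at 0 h pushes them up and down and members go both ways (19 of the lowest below 0, 31 above).

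Some histone mRNAs stood higher with Cugbp1 siRNA, H2bc4 most. More cells in S phase would raise replication genes, whose median level difference was −0.0483. Signal shared with the 4 other tested H2B genes would raise them, and their median 0 h difference was 0.0044 against 1.54 for H2bc4. Only 17 of the 32 histone genes named on the array were tested, so signal shared with an untested paralog is not excluded. A rise limited to histone transcripts that outlast transcription arrest was read from these 17 genes, so their correlation with the fall in the Mbnl1 arm (Spearman rho = 0.5441) cannot support it and it stays open. The 4 that fell less than 2-fold there had a median 0 h difference of 0.296 and the 13 others 0.0522, but H2ax and H2aw were higher (0.44 and 0.223) though they fell (−1.378 and −1.604), and H4c9 fell little (−0.42) and was not higher (−0.051). Slbp, which binds histone mRNA, was lower with both siRNAs (−0.91 with Cugbp1 and −0.44 with Mbnl1 siRNA), and H2bc4 was higher with both.

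As a group the 986 fastest-falling mRNAs fell less in the Cugbp1 arm, but histones did not: their median change at 2.5 h was −2.47 there and −2.02 in the control arm, with 5 declining faster and 3 slower adjusted over the list alone, and members that go both ways leave compression undecided. With compressed changes or a weaker transcription block in that arm, genes that rise should rise less there; at 5 h the tenth that rose most in the Mbnl1 arm differed by 0.0236, which met the bound set against this explanation, but that bound ignored the shift of all genes (0.0471). Minus the median of all genes the values were −0.0235 at 5 h and −0.0154 at 2.5 h, the direction compression predicts, with 0.0236 and 0.0132 for these genes below the random ranges (0.0439 to 0.0609 and 0.0236 to 0.0381). Equal ribosomal protein medians left the gap to other mRNAs at 0.017 per h, as a shift of whole arrays must, with medians of 0.0114 and −0.0056 per h. Compression, a difference between single cultures and slower decay without Cugbp1, which was not tested apart from these, may each account for it. With Mbnl1 siRNA the fast-decaying mRNAs also declined less than in the control arm as deposited (0.0102 per h). Between the knockdowns the top 10% did not pass (camera adjusted p = 0.216). A difference of the single control series is thus not told apart from one of the Cugbp1 arm.

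Other divisions of the arrays are too few for a share under 0.05. For the 5 time and level contrasts 1 of the 10 splits of 6 arrays, the real one, gave as many genes, with real counts of 6746, 4674, 1894, 5426 and 5563 and a highest other count of 0 each. Swapping siRNA labels within a time gives 4 ways for decay: for Cugbp1 siRNA all 4 gave the real count of 0, and for Mbnl1 siRNA (real count 2) and between the knockdowns (93) 1 of 4 did, with a highest other count of 0.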

How the results depend on the processing

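The estimated correlation and equal ribosomal protein medians for fast-decaying mRNAs and the fits without the Mbnl1 arrays (5971 genes at 5 h and 3785 at 2.5 h) were chosen after the data had been seen. The cause of a change in these counts was not tested. With a filter at the 70th percentile the counts were 4240 at 5 h, 3091 at 2.5 h, 111 for decay under Mbnl1 siRNA and 200 for decay between the knockdowns. Equal ribosomal protein medians gave 1234 for the level under Cugbp1 siRNA and 295 and 355 for these decay contrasts. They turned Actb at 5 h to −0.21, the only reversal among named genes. Fast-decaying mRNAs under Mbnl1 siRNA turned to −0.0182, but the other genes then lay lower still, at −0.0278. The sign changed for 12 of 27 list medians at 5 h, 12 at 2.5 h, 15 for decay under Mbnl1 and 11 under Cugbp1 siRNA. With no filter the level under Cugbp1 siRNA had 969 genes, both decay contrasts had 0, and the correlation of slopes was 0.379. Trended and robust moderation gave 4 for decay under Cugbp1 siRNA, 198 under Mbnl1 siRNA and 322 between the knockdowns; the mean of probe sets gave 21 under Mbnl1 siRNA; only the 2 siRNAs compared gave 0 and 33, and no shared curvature gave 0 and 0. Leaving out 1 array gave 6015 to 6597 at 5 h, 3128 to 4856 at 2.5 h, 742 to 2027 for the level under Cugbp1 siRNA (lowest without the control array at 2.5 h, 759 without the Cugbp1 array at 2.5 h), 4455 to 5480 under Mbnl1 siRNA, 4574 to 5472 between them, 0 throughout for decay under Cugbp1 siRNA, 0 to 203 under Mbnl1 siRNA and 0 to 474 between them (both highest without the Mbnl1 array at 2.5 h). With an estimated correlation, which also tests on the few residual degrees of freedom, 0 lists were called in any of the 8 contrasts. With equal ribosomal protein medians 0 were called under Cugbp1 and 3 under Mbnl1 siRNA in level. For fast-decaying mRNAs the median slope difference with an estimated correlation was 0.0252 under Cugbp1 siRNA (camera p = 0.228) and 0.0102 under Mbnl1 siRNA (p = 0.472), neither past the threshold. The top 20% gave 0.0044 under Mbnl1 siRNA (camera p = 0.254) and −0.0167 between the knockdowns (p = 0.0352, 0.429 with an estimated correlation). Over 144 named gene and comparison pairs, 1959 of 2212 alternatives kept direction and side of the threshold, 222 lost the call, 28 gained it, 1 reversed and 2 moved without a call. The GU-rich and YGCY motif test was not run. How far signal stood above background on each array was not analysed here.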

Other observations

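Among the 3974 probe sets without a single gene symbol, 1766 were higher and 477 lower at 5 h, 26 higher and 51 lower with Cugbp1 siRNA, and 379 higher and 471 lower with Mbnl1 siRNA. A second Celf1 probe set, not used in the fits, stood at 27.5%, 23.4% and 24.1% of control with Cugbp1 siRNA at 0, 2.5 and 5 h, and at 78.9%, 53.5% and 49.2% with Mbnl1 siRNA.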
